A study of Mus musculus with 2 samples.

How the data were processed

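The series compared CD11b+ cells of subcutaneous tumours, grown from mouse pancreatic cancer cell lines in mice with a floxed Nrp2 gene and a tamoxifen-inducible Csf1r-driven Cre recombinase. The labels describe a control group and a test group given daily tamoxifen to delete Nrp2, harvest at 15 days, bead isolation of CD11b+ cells and RNA pooled from 3 animals per group. Groups were taken from the sample titles, and each group has 1 library. The labels give both samples the same genotype, since the deletion was induced.

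Libraries were made with a TruSeq stranded mRNA kit, per the labels' protocols. The submitters' processing notes name cutadapt for trimming, HISAT2 for alignment, featureCounts for counting and the GRCm38 genome, with no versions or options, and the annotation release is not given in the sources used here. Per the file headers, the count columns hold read 1 of each library. The authors deposited whole-number counts of reads per Ensembl gene, with no normalisation. They also deposited a comparison table, whose header has the column names that DESeq2 writes. In it the normalised values are a signal obtained from the deposited counts by dividing each library by a constant, 0.995 for the control library and 1.01 for the knockout library, as a check on the values showed. The same deposited table gives the log2 fold change, its standard error on the log2 scale, a score that is their quotient, and a p-value and adjusted p-value per gene. The tool, options and version behind that table are not given in the sources used here. No molecular identifiers are named, so PCR duplicates are counted as reads. Whether counting used the strand is not stated, so reads of overlapping genes on opposite strands are uncertain.

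The count table held 49585 gene identifiers, of which 49326 matched a symbol in the GENCODE mouse annotation (release M21, GRCm38), from which coordinates, GC content and transcript lengths were also taken. The 259 unmatched identifiers kept their identifiers. Reads were present in both libraries for 14959 genes, in one library only for 3905 and in neither for 30721. The libraries held 64153676 and 68554172 counts, and the 10 most counted genes took 10.1% of the control and 10.3% of the knockout library.

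Library sizes were normalised with TMM factors from edgeR 4.0.16 in R 4.3.3, which were 1.02 for the control and 0.976 for the knockout library. Log2 ratios, knockout over control, were computed from normalised counts with a prior of 0.5 counts per library, for 14420 genes with at least 50 counts over both libraries. Levels are given as CPM computed with the normalised library sizes. With 1 library per group no residual degrees of freedom remain, so no test across genes was run, and genes were described by a rule of size, at least 2-fold. The 95% interval of a ratio is the exact conditional Clopper-Pearson interval. As planned it was computed on reads. After the data were seen it was also computed on reads divided by the reads per fragment, because genes seen in one library only, with more than 4 reads, had a median of 47 reads in the control library (867 genes) and 24 in the knockout library (2114 genes). The fragment-scaled interval is the one printed unless stated otherwise, and the floor for a count of 0 is 3 fragments. The robust SD of the log2 ratio was 4.06 for genes with 50 to under 100 counts and 0.40 for genes with at least 10000. To see how many genes pass 2-fold with no true difference, 20 pairs of libraries were simulated as Poisson fragments from the mean of both libraries and multiplied by the reads per fragment. Every fragment of a library was given the same number of reads, and no differences between animals were simulated.

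The named genes follow a rule set before the data were examined. It takes Nrp2, Nrp1, Itgam, Csf1r, Adgre1, Ptprc, Mertk and Axl. It adds the 12 largest ratios in each direction among genes with at least 200 counts in the higher library and a read interval wholly past 2-fold, without predicted and RIKEN genes. It further takes up to 4 members of each gene list with the largest absolute ratio and at least 50 counts, and the 10 most counted genes. The 12 largest ratios per direction with at least 2000 counts in the higher library, and the genes of the lists tested in the closing section, were chosen after the data were seen. So were well-read members of the monocyte, neutrophil and alternative activation lists that the rule does not take. Some of the genes this rule takes are not reported here.

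The 40 gene lists were fixed from general knowledge before the data were examined: cell type markers (macrophage, monocyte, neutrophil, conventional and plasmacytoid dendritic cell, T cell, NK and cytotoxic lymphocyte, B cell, mast cell and basophil, eosinophil, erythroid and platelet, epithelial tumour cell, fibroblast, endothelial, skin keratinocyte, skeletal muscle, adipocyte), macrophage functions, interferon and antigen presentation, complement, the neuropilin axis, angiogenesis, and stress and housekeeping groups. Lists share members, and 13 of 24 macrophage genes are also on another list. Each list's median log2 ratio was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. A list stands apart under percentile 2.5 or over 97.5 with at least 5 measured members, and 1 list, the sex-linked genes, had fewer. Members of a list vary together, so percentiles are not p-values.

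The procedures were tested on simulated data. With reads drawn independently, 100% of 95 genes set to 4-fold and 99.0% of 96 set to 3-fold passed 2-fold, and 0.07% of unchanged genes did. With amplified fragments, 94.7% of 95 and 81.3% of 91 did, and so did 11.2% of unchanged genes, or 0.76% of those with at least 1000 counts. Of 1000 random lists, 5.8% and 6.0% fell outside the limits in the 2 simulations.

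Alternatives set before the data were examined were DESeq2 1.42.0 size factors, total counts or upper-quartile scaling, no count filter or at least 200 counts, a prior of 5 counts, limits of 1.5-fold and 3-fold, thinning to the smaller read total, unmatched random lists, members that no other list holds, and counts without other cell types' genes. Added after the data were seen were a filter of at least 1000 counts, removal of a lowess trend (span 0.3) on GC content and transcript length, the fragment-scaled intervals, and holding genes at 0 in one library, in the lists and the random lists alike, at their bounds. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.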

Results

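Messenger RNA was sequenced from CD11b+ cells of subcutaneous pancreatic tumours in mice. CD11b (Itgam) is an integrin of monocytes, macrophages, granulocytes and part of the dendritic cells, and the cells were pulled from digested tumours with magnetic beads. Per the labels, both groups came from a line with a floxed Nrp2 gene and an inducible Cre recombinase under the Csf1r promoter, which is active in monocytes and macrophages. The test animals received tamoxifen, which activates the recombinase and deletes Nrp2, once tumours were palpable. The labels name no tamoxifen for the controls, so the drug and the deletion differ together between the groups. Tumours were harvested at 15 days, and RNA from 3 animals was pooled into 1 library per group. The control library held 64153676 counted reads and the knockout library 68554172, over 16257 and 17566 detected genes.

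With 1 pooled library per group there are no replicates, so no difference below has a replicate check and no p-value was computed. A low-count pattern set the precision. Genes with more than 4 reads in one library and none in the other had a median of 47 reads in the control library and 24 in the knockout library, where single sequenced molecules would give a few. A captured fragment was therefore taken as worth 47 and 24 reads, and the intervals below are 95% exact Clopper-Pearson intervals of the ratio on counts divided by these values. They cover counting error only, with every fragment taken as worth the same reads, and not differences between animals. A count of 0 allows up to 3 fragments, or 141 reads in the control library and 72 in the knockout library, and folds against a library at 0 are bounds against that floor. These bounds leave out the counting error of the other library, so the 95% interval of the ratio can start lower.

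**Figure D1:**
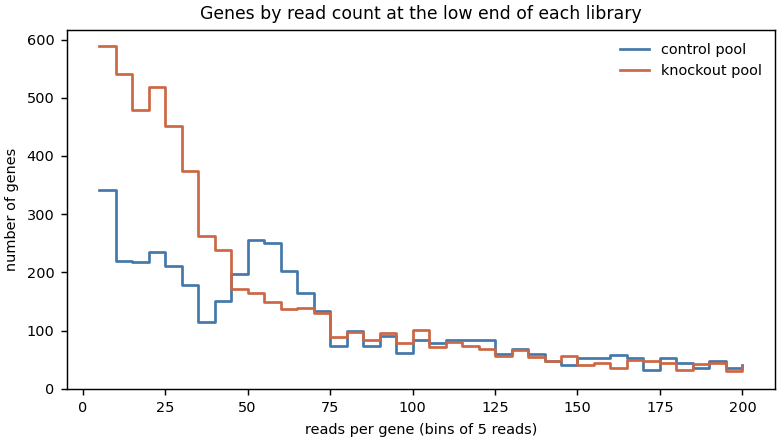
Number of genes (vertical axis) by reads per gene in bins of 5 reads from 5 to 204 (horizontal axis), for the control and knockout pools. The control pool has a separate peak of 255 genes at 50 to 54 reads, and the knockout pool falls from 588 genes at 5 to 9 reads with a small rise to 518 at 20 to 24.

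The comparison asked how the transcriptome of tumour CD11b+ cells differs when Nrp2 is deleted from myeloid cells, and the clearance of apoptotic cells is among the processes this study is about. Nrp2, the targeted gene (ENSMUSG00000025969, GRCm38 chromosome 1, 62703285 to 62818695, plus strand), encodes neuropilin 2, a co-receptor for class 3 semaphorins and VEGF-C. It had 9686 reads in the control library and 1017 in the knockout library, or 147 and 15.2 CPM after normalisation, and was 9.7-fold lower in the knockout library (95% interval 6.94 to 13.8). The interval on undivided reads was 9.09 to 10.4. Its paralogue Nrp1 was at 97.6 and 103 CPM, a ratio of 1.05 whose interval of 0.855 to 1.3 includes 1 and whose direction turned under upper-quartile scaling (log2 ratio -0.0012).

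Among 14420 genes with at least 50 reads over both libraries, 1566 were at least 2-fold higher and 2118 at least 2-fold lower in the knockout library, 3684 in all. Most of these folds rest on few fragments, and libraries simulated from amplified fragments with no true difference gave 1520 ± 24.5 genes (SD over 20 simulations). The simulation gave every fragment of a library the same number of reads, although 342 genes had 5 to 9 reads in the control library. It also held no differences between animals. The excess over it is therefore not a count of genes that differ because of the treatment. The interval lay wholly past 2-fold for 123 genes that were higher and 148 that were lower. At 0 in one library were 792 genes, whose fitted fold depends on the prior count, and with these held at their bounds 1194 genes were higher and 1745 lower. Of the 9054 genes with at least 1000 reads, a limit added after the data were seen, 410 were higher and 362 lower, where the simulation gave 69.4 ± 9.58 in all.

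The 12 genes with the largest fold under the rule fixed beforehand were all at 0 in the control library when higher in the knockout library, so their rank rests on the prior count. They were led by Orm1, an acute-phase plasma protein gene with 1193 reads in the knockout library, 8.31-fold higher against the floor of the control library. Pdk4, a kinase that inhibits pyruvate dehydrogenase, was 3.34-fold higher against that floor. Adipoq, the adipocyte hormone adiponectin, was 3.16-fold higher against it, with an interval that starts at 2.33-fold. The others were Prg4, Cyp2e1, Hif3a, Cited1, Cabyr, Pdzd2, Ogdhl, Jcad and Mapt, with bounds from 2.99-fold down to 1.76-fold. Of the 12 genes with the largest fold in the other direction, 11 were at 0 in the knockout library, and their rank rests on the prior count too. Ifi202b, an interferon-inducible gene, had 3649 reads in the control library and was 51.6-fold lower against the floor of the knockout library. Its expression is known to differ between inbred mouse strains, and beyond one shared strain label the background of the pooled animals is not given in the sources used here. Cyp2g1, Gimap7, Aplnr, Fmod, Itga8, Npdc1, Armcx4, Gp2, Tox and Ksr2 had bounds from 9.38-fold to 3.01-fold. The immunoglobulin gene Ighg2b had 906 reads against 1, a ratio whose interval starts at 9.23-fold. Ifi202b and Ighg2b belong to families of near-identical genes, among which the counting could split reads, and so do Chil3, Cd209a, Cd209g, Ifit3b, Tgtp2, Klra8 and the other immunoglobulin and haemoglobin genes named below.

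Genes with at least 2000 reads in the higher library, a limit chosen after the data were seen, gave better-supported folds. Saa3, an acute-phase serum amyloid, was at 70 and 1908 CPM in the control and knockout libraries, 27.3-fold higher (22.3 to 33.7). Chil3, a chitinase-like protein of monocytes and alternatively activated macrophages, was at 338 and 6072 CPM, 18-fold higher (16.4 to 19.7). Esr1, the oestrogen receptor alpha gene, was 35.4-fold higher (21.5 to 63), and gene-level counts do not tell its reads from those of a recombinase fused to this receptor. Fkbp5, a co-chaperone of steroid receptors, was 18.7-fold higher (13.1 to 27.5), and Klf9, a transcription factor, 10.5-fold (5.9 to 20.5). Also higher were Zfp949, Cfd, C77080, Lcn2, Fbxo32, Apod and Gpnmb, with folds of 46.5 to 7.57. Lower in the knockout library were Fcrls, an Fc receptor-like gene of macrophages, at 16.8-fold (12.9 to 22.1), and Cd72, at 10.8-fold (7.55 to 15.9). The lectin genes Cd209a, Mgl2 and Cd209g were 20.7-fold (9.14 to 56.7), 10.4-fold (8.61 to 12.8) and 9.37-fold (4.57 to 21.5) lower. Igha, Gja1, Igkc, Pxdc1 and Ighm were between 10.1-fold and 20.9-fold lower, and Ifi202b and Nrp2 completed the 12.

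**Figure D2:**
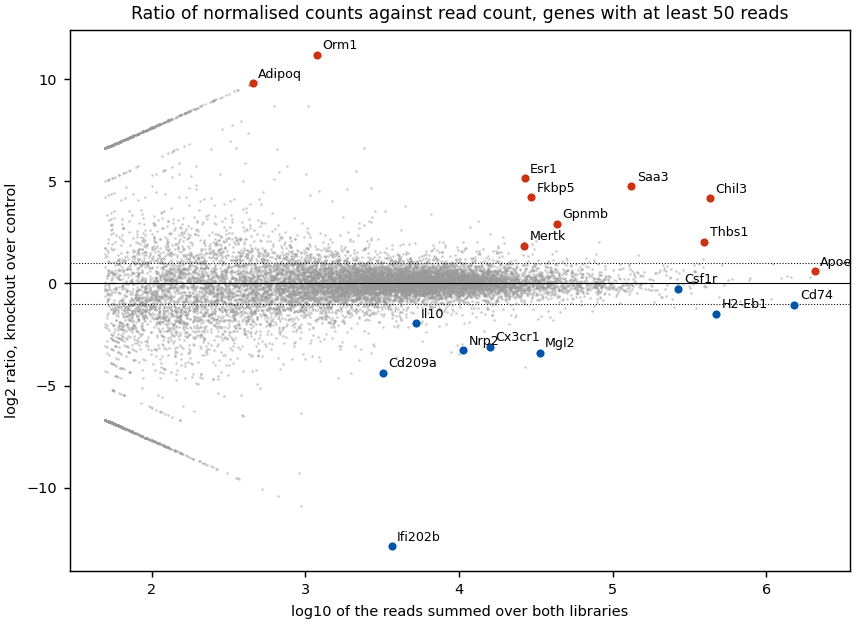
Log2 ratio of normalised counts, knockout over control (vertical axis), against log10 of the reads summed over both libraries (horizontal axis), for genes with at least 50 reads in all. Grey points are genes, red points are named genes that were higher and blue points named genes that were lower in the knockout library; dotted lines mark 2-fold and the straight outer lines of points are genes at or near 0 in one library. The spread narrows as reads increase, and Nrp2 lies at -3.28, Saa3 at 4.77 and Cd74 at -1.04.

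Gene lists fixed before the data were examined were compared with 10000 random lists of the same size matched on mean expression, and a list was said to stand apart when its median log2 ratio lay among the lowest or highest 2.5% of theirs. These percentiles describe the 2 libraries. Of 39 lists with at least 5 measured members, 3 stood apart as higher in the knockout library and 17 as lower. If genes and lists varied independently, 1.95 would fall outside. Members of a list vary together and lists share members, so more could fall outside between any 2 pools, and the numbers are not a test.

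Macrophage genes as a group did not stand apart: of 24 members, 3 were at least 2-fold higher and 1 at least 2-fold lower (median log2 ratio 0.17, percentile 92.0). The list stood apart as higher once a trend with GC content and transcript length was removed (percentile 98.9), and as lower on the 11 members that no other list holds (percentile 1.96). Itgam was 1.44-fold higher (1.28 to 1.61), while the growth factor receptor gene Csf1r was 1.19-fold lower (1.14 to 1.25), Adgre1, which encodes F4/80, 1.37-fold lower (1.26 to 1.49) and the pan-leukocyte gene Ptprc 1.35-fold lower (1.25 to 1.47). The members with the largest ratios were Gpnmb, a glycoprotein of lysosome-rich macrophages, at 7.57-fold higher (6.21 to 9.29), Mertk at 3.58-fold higher (2.96 to 4.37), Lyve1 at 2.24-fold higher (1.69 to 3.0) and Aif1 at 2.58-fold lower (2.28 to 2.93). Monocyte genes went both ways, with 6 of 18 at least 2-fold higher and 6 at least 2-fold lower (median -0.20, percentile 3.77). The 15 of them that no other list holds stood apart as lower, at a median of -0.76. Chil3 was higher, whereas Cx3cr1 and Treml4, which mark patrolling monocytes, were 8.56-fold (6.58 to 11.3) and 9.21-fold (3.99 to 24.8) lower, and Cd300e had 130 and 20 reads. Nr4a1, on the same list, was at a ratio of 1.03 (0.95 to 1.13). Ly6c2 was 2.75-fold higher, and Ccr2 and Plac8 were 2.66-fold and 3.15-fold lower, so the lower genes were not only those of patrolling monocytes.

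Neutrophil genes stood apart as higher in the knockout library, with 10 of 22 at least 2-fold higher and 2 at least 2-fold lower (median 0.77, percentile 100). With the 2 members at 0 in one library held at their bounds the median was 0.28 (percentile 97.8 among random lists treated alike), and among members with at least 1000 reads the list no longer stood apart (median 0.27, percentile 94.3). The granule gene Ngp had 2 reads in the control library and 1033 in the knockout library, a ratio whose interval starts at 5.47-fold, and Stfa2 had 2 and 320, starting at 1.53-fold. Ly6g with 96 reads and Elane with 51, both at 0 in the control library, lay under its floor. Some members with more reads in the control library were higher too. Lcn2 was 9.46-fold higher (from 4.06), Wfdc21 7.28-fold (from 3.24), Ltf 3.17-fold (from 1.43) and Stfa2l1 2.73-fold (from 1.61). Among the most-read members, S100a8, S100a9 and Trem1 were 1.93-fold, 1.52-fold and 1.47-fold higher. Csf3r was at a ratio of 0.99, and Il1r2, Retnlg and Mmp9 were 1.15-fold, 1.24-fold and 3.04-fold lower. Conventional dendritic cell genes were lower as a group, with 10 of 18 members at least 2-fold lower and 0 at least 2-fold higher (median -1.08, or -0.94 with Xcr1 at its bound; percentile 0). Clec9a, a receptor of cross-presenting dendritic cells, was 3.93-fold lower (1.69 to 9.83), the chemokine Ccl22 3.13-fold lower (2.51 to 3.92), and Xcr1 had 111 reads against 0. Plasmacytoid dendritic cell genes did not stand apart (median 0.02, or -0.01 with 1 member at its bound; percentile 59.2); of these Lag3 was 2.67-fold lower (1.76 to 4.07), and the intervals of Klk1 and Ly6d included 1. Eosinophil genes were lower, with 4 of 8 at least 2-fold lower and 2 at least 2-fold higher (median -0.85, percentile 0.02). Alox15, Ccr3 and Siglecf were 3.87-fold, 3.53-fold and 2.61-fold lower, and Ear6 was 5.52-fold higher (2.0 to 21.2). Mast cell and basophil genes did not stand apart (median -0.05, percentile 57.5), although Tpsab1, a mast cell tryptase, was 6.53-fold higher (1.15 to 159).

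T and B cell genes, which a CD11b selection should largely exclude, and genes of NK cells, part of which carry CD11b, were detected in both libraries and were lower in the knockout library. In the T cell list 22 of 26 members were at least 2-fold lower and 0 at least 2-fold higher (median -1.68, percentile 0). The summed reads of this list were 22374 and 7990, a 2.85-fold difference. Cd8b1, a chain of the CD8 co-receptor, was 11.6-fold lower (2.22 to 148) and the transcription factor Tcf7 7.54-fold lower (1.74 to 53.9); Skap1 and Cd5 were 11.4-fold and 5.02-fold lower. Among NK and cytotoxic lymphocyte genes 18 of 23 were at least 2-fold lower and 1 at least 2-fold higher (median -1.50, percentile 0). The granzyme gene Gzmc was 7.6-fold lower (2.27 to 34.9), and Klra8, Cd160 and Eomes were too shallow for an interval that excludes 1. Of 13 B cell genes 10 were at least 2-fold lower and 0 at least 2-fold higher (median -1.91, or -1.41 with Pax5 at its bound; percentile 0.02). The immunoglobulin genes Igkc, Ighm and Jchain were 12.3-fold (6.71 to 24.6), 10.1-fold (6.94 to 15.1) and 9.43-fold (2.28 to 67.1) lower. Cell cycle genes were lower beside these lists: 23 of 36 members were at least 2-fold lower and 0 at least 2-fold higher (median -1.36, percentile 0). Birc5, a regulator of mitosis and apoptosis, was 5.57-fold lower (2.49 to 13.7), Ccna2, which encodes cyclin A2, 4.37-fold (2.14 to 9.46), and Ube2c and Cdc20 were 4.54-fold and 3.96-fold lower. Replication-dependent histone genes did not stand apart (median -0.73, -0.29 with 4 members at their bounds, percentile 24.8), and poly(A) selection captures their transcripts poorly.

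Epithelial tumour cell genes were lower in the knockout library (9 of 20 at least 2-fold lower, 2 at least 2-fold higher; median -0.87, -0.75 with 2 members at their bounds, percentile 0.15), among them Muc1 with 242 and 9 reads. Fibroblast genes were lower too (7 of 20 against 1 higher; median -0.80, percentile 0), with Thy1, which is also on the T cell list (median -1.68), 3.48-fold lower (2.07 to 5.97). Endothelial genes stood apart as lower (9 of 17 against 2 higher; median -1.01, percentile 1.36), but this call rests on the prior count. With Sox17 and Sox18, at 0 in one library, held at their bounds, 7 were at least 2-fold lower and the list no longer stood apart (median -0.69, percentile 2.74 among random lists treated alike). Of its members Plvap was 5.36-fold lower (1.33 to 29.9) and Esam 9.04-fold lower (1.35 to 179.6). The 5 measured erythroid and platelet genes were lower as a group (median -1.44, percentile 1.02), 3 of them at least 2-fold, among them Ppbp at 2.72-fold (1.53 to 4.92); the others were haemoglobin genes, with 183 and 31 reads of Hbb-bs and 71 and 16 of Hba-a1. Skin keratinocyte and skeletal muscle genes did not stand apart (medians -1.0 and -1.08, the latter -0.54 at the bounds, percentiles 9.81 and 10.1), although against random lists not matched on expression both did (percentiles 0.66 and 0.13). Krt14, a basal keratin, was 8.32-fold lower (3.72 to 21.2). Adipocyte genes went the other way and stood apart as higher, with 8 of 11 at least 2-fold higher and 0 lower (median 2.20, 1.18 with 3 members at their bounds, percentile 100). Car3, a carbonic anhydrase abundant in fat and muscle, was 23.2-fold higher (4.14 to 773), and Plin1 and Retn had 170 and 192 reads against 0. Of the sex-linked genes 2 had enough reads, too few for a list, and Xist was at 249 and 353 CPM.

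Genes of MHC class II antigen presentation were lower in the knockout library. Of 14 genes 6 were at least 2-fold lower and 0 at least 2-fold higher (median -0.88, percentile 0). Cd74, the invariant chain and the most counted gene of the control library, was at 15536 and 7546 CPM, 2.06-fold lower (2.02 to 2.1). H2-Eb1 was 2.81-fold lower (2.71 to 2.91), H2-Aa 1.68-fold (1.64 to 1.72), H2-Ob 5.13-fold (2.62 to 10.7) and Ciita, the class II transactivator, 2.39-fold (1.97 to 2.91). The protease gene Ctss, also on this list, was 1.91-fold higher (1.87 to 1.96). Dendritic cell and B cell genes, whose cells carry much class II, were lower in the same library (medians -1.08 and -1.91). None of 21 MHC class I genes reached 2-fold, yet the list was lower as a group (median -0.31, percentile 0.12). It did not stand apart from random lists not matched on expression (percentile 4.68). The immunoproteasome genes Psmb9 and Psmb8 were 1.84-fold (1.54 to 2.19) and 1.69-fold (1.51 to 1.88) lower, and Psme2 and Tapbpl 1.76-fold and 1.67-fold. Interferon gamma response genes were lower, 5 of 28 by at least 2-fold and 0 higher by as much (median -0.54, percentile 0), beside the lower T and NK cell genes (medians -1.68 and -1.50). The chemokine gene Cxcl11 was 2.58-fold lower (1.5 to 4.48) and Tgtp2 2.32-fold lower (1.5 to 3.59). Type I interferon genes did not stand apart (median 0.02, percentile 37.5): Slfn4 was 4.23-fold higher (3.52 to 5.13), Rsad2 2.48-fold higher (2.02 to 3.07) and Ifit3b 8.25-fold higher (1.46 to 218).

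Genes of IL-4-associated alternative activation were lower as a group, with 9 of 25 at least 2-fold lower and 2 at least 2-fold higher (median -0.37, percentile 0). Its members differed in direction, with 8 higher and 17 lower at any size. Chil3 was 18-fold higher, the lectin genes Mgl2 and Cd209a, also used as dendritic cell markers, were over 10-fold lower, and Chil4 had 20 and 176 reads. Arg1, Cd163 and Mrc1 were 1.91-fold (1.83 to 1.99), 1.93-fold (1.62 to 2.31) and 1.64-fold (1.56 to 1.73) higher. Other well-read members were lower: Ccl24 by 5.05-fold (12193 and 2457 reads), Cd209d by 4.34-fold, Alox15 by 3.87-fold, Ccl22 by 3.13-fold and Ccl17 by 1.77-fold. Classical inflammatory genes did not stand apart (median -0.04, percentile 21.5), with 3 of 32 at least 2-fold higher and 4 at least 2-fold lower. Besides Saa3, the scavenger receptor gene Marco was 2.78-fold higher (1.82 to 4.41), Il12b, a subunit of interleukins 12 and 23, was 5.23-fold lower (1.67 to 20.1), and the interval of Il12a included 1. Immune regulatory and checkpoint genes were lower (median -0.36, -0.31 with Il13 at its bound, percentile 0.08), 6 of 24 by at least 2-fold and 1 higher by as much, beside the lower T and NK cell genes (medians -1.68 and -1.50). Il10, an anti-inflammatory cytokine, was 3.88-fold lower (2.68 to 5.69) and Tigit, a checkpoint receptor of T and NK cells, 5.22-fold (1.67 to 19.9), while the interval of Il4 included 1. Among members with at least 1000 reads this list no longer stood apart (median -0.14, percentile 6.18).

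Genes of apoptotic cell recognition and engulfment did not stand apart as a group: 6 of 41 were at least 2-fold higher, 3 at least 2-fold lower and 32 within 2-fold (median 0.09, percentile 75.4). Mertk, a receptor tyrosine kinase that binds apoptotic cells through bridging proteins, was at 86.7 and 310.3 CPM, 3.58-fold higher in the knockout library (2.96 to 4.37). Its relative Axl was 1.43-fold lower (1.32 to 1.55). Thrombospondin 1 (Thbs1), a bridging protein, was 4.11-fold higher (3.9 to 4.33) at 1160.2 and 4764 CPM, and Itgb3, a chain of the vitronectin receptor, 3.75-fold lower (1.97 to 7.39). Adgrb1, a phosphatidylserine receptor, had 240 reads against 0 and was 1.67-fold higher against the floor of the control library, with an interval from 1.12-fold. The interval of Stab2 included 1. Phagosome and lysosome genes lay close to the upper limit (median 0.17, percentile 95.3), and 43 of 47 were within 2-fold. The list stood apart as higher among members with at least 1000 reads (percentile 97.8) and after removal of the GC and length trend (percentile 98.3). Atp6v0d2, a proton pump subunit, and Ctsk, cathepsin K, were 3.89-fold (3.09 to 4.94) and 2.47-fold (1.6 to 3.94) higher, Ctsc, cathepsin C, was 2.24-fold lower (2.14 to 2.35), and the interval of Rab34 included 1. Lipid handling and LXR target genes stood apart as higher, 5 of 22 by at least 2-fold and 1 lower by as much (median 0.51, percentile 99.97), beside the higher adipocyte genes (median 2.20). Gpnmb was 7.57-fold higher, and the fatty acid binding protein gene Fabp4, on both lists, was 4.61-fold higher (2.48 to 9.46). The apolipoprotein genes Apoc4, Apoc1 and Apoe were 7.83-fold (2.15 to 56.3), 3.35-fold (1.3 to 11.1) and 1.51-fold (1.48 to 1.54) higher, and Apoe was the most counted gene of the knockout library. Sterol synthesis genes did not stand apart (median -0.06, percentile 23.1), and none reached 2-fold.

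Neuropilin, plexin, semaphorin and VEGF genes, a list that leaves out Nrp2, were lower in the knockout library: 9 of 26 at least 2-fold lower and 1 at least 2-fold higher (median -0.54, -0.47 with Sema3a at its bound, percentile 0.10). Its largest ratios rest on few reads. The plexin genes Plxna4 and Plxna3, which encode semaphorin receptors, had 232 and 336 reads in the control library and were 9.84-fold (1.09 to 467) and 5.26-fold (1.16 to 35) lower. The endothelial median beside them was -1.01, or -0.69 at the bounds. Angiogenesis and matrix remodelling genes went both ways and did not stand apart (5 of 33 at least 2-fold higher, 7 at least 2-fold lower; median -0.09, percentile 14.8). Ecm1, an extracellular matrix protein, was 4.14-fold higher (3.69 to 4.65), whereas the growth factor gene Pdgfb and the collagenase gene Mmp13 were 4.19-fold (2.69 to 6.68) and 3.36-fold (2.92 to 3.87) lower. Complement genes did not stand apart (median 0.06, percentile 65.2), although Cfd and Vsig4, a complement receptor of resident macrophages, were 11.7-fold (5.04 to 35) and 7.74-fold (3.28 to 23.2) higher, and Itgax, which encodes CD11c, was 2.09-fold lower (1.9 to 2.3).

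Stress and housekeeping lists had medians between -0.24 and 0.06. Hypoxia and glycolysis genes (median -0.13, percentile 5.0), immediate early and heat shock genes of cell isolation (0.06, 64.7) and ribosomal protein genes (-0.07, 11.8) did not stand apart. Klf2 was 2.75-fold higher (2.39 to 3.19) and the heat shock gene Hspa1b 2.09-fold lower (1.53 to 2.86). Mitochondrially encoded genes (-0.24, 10.2) and unfolded protein response genes (-0.09, 10.6) did not stand apart either, but both did as lower among members with at least 1000 reads (percentiles 0.83 and 1.53). Of the latter Ddit3, a stress-induced transcription factor, was 3.79-fold higher (2.39 to 6.31). Nuclear genes of oxidative phosphorylation were slightly lower (-0.18, percentile 0.25), with none of 32 at 2-fold. That call was lost after removal of the GC and length trend, where the median was 0.0149, and against unmatched random lists (percentile 10.2).

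**Figure D3:**
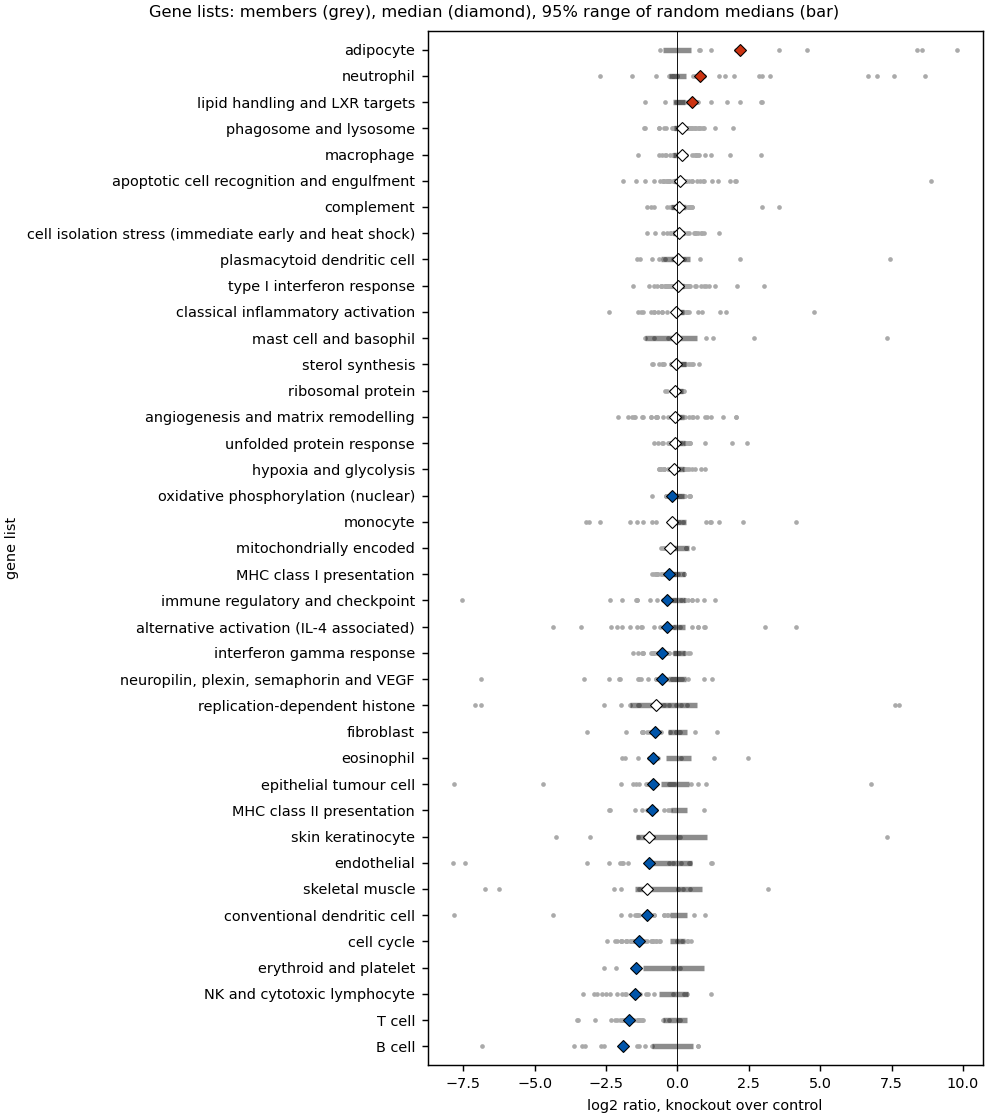
Log2 ratio, knockout over control (horizontal axis), for the members of each of 39 gene lists (vertical axis), as grey points. Diamonds are list medians (red higher, blue lower, white not standing apart) and bars the 95% range of medians of matched random lists; points beyond 6 either way are genes at or near 0 in one library. The adipocyte median lies at 2.20, the cell cycle median at -1.36 and the B cell median at -1.91.

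The authors' deposited table of their own comparison listed log2 fold changes for 18864 genes. Over 14959 genes with reads in both libraries, the ratios computed here without the prior count differed from it by at most 0.0118 on the log2 scale. This is a shift from the normalisation, and 99.3% had the same sign. In the authors' deposited table Nrp2 had a log2 fold change of -3.27 with a standard error of 0.91 and ranked 16 by p. No gene there had an adjusted p under 0.05, the smallest being 0.331, and 794 had an unadjusted p under 0.05. Those p-values come from 1 library per group and are not used here.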

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

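The filter of at least 1000 counts, the removal of the GC and length trend, the fragment-scaled intervals and the holding of genes at 0 at their bounds were chosen after the data were seen. Leaving out a library was not possible with 1 per group. No paired analysis was possible because each group is 1 pooled library. Sequencing depth was high, but the number of captured fragments limits genes under about 1000 counts.

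Under the 3 other scalings the number of genes at least 2-fold higher or lower stayed between 3686 and 3696, and with a prior of 5 counts, thinning to the smaller read total, no genes of other cell types or the trend removed between 3570 and 3639. It was 2939 with genes at 0 in one library held at their bounds (1194 higher, 1745 lower), 7406 with no filter (4140 higher, 3266 lower), 1820 with at least 200 counts (832 and 988) and 772 with at least 1000 (410 and 362), where each filter changes which genes are counted. The share that was higher, 42.5% as reported, was 55.9% with no filter and 53.1% with at least 1000 counts. At 1.5-fold 6146 genes passed (2873 and 3273) and at 3-fold 2256 (925 and 1331), by construction.

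Of 418 list values under alternatives, 402 kept their side of the limits. This number includes the 3 other scalings, which shift every log2 ratio by the same amount and so cannot move a list's percentile. The values under those scalings kept their side by construction. With at least 1000 counts the neutrophil median was 0.27 (percentile 94.3) and the immune regulatory median -0.14 (6.18), both inside the limits, on fewer members (16 and 20). With genes at 0 held at their bounds the endothelial median was -0.69 (percentile 2.74), inside the limits, since 2 members move toward 0. The oxidative phosphorylation median turned to 0.0149 (percentile 34.9) with the trend removed, so its direction depends on that trend, which across genes had a Spearman rho of -0.16 with GC content and 0.26 with length. Unmatched random lists put oxidative phosphorylation at -0.18 (percentile 10.2) and MHC class I at -0.31 (4.68) inside the limits.

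Lists inside the limits as reported passed them in 10 cases, and the cause was not tested. With at least 1000 counts these were phagosome and lysosome (0.20), unfolded protein response (-0.18) and mitochondrially encoded genes (-0.42). With the trend removed they were macrophage (0.29) and phagosome and lysosome (0.21). Against unmatched lists they were keratinocyte (-1.0), skeletal muscle (-1.08) and histone genes (-0.73), and among members no other list holds macrophage (-0.26) and monocyte genes (-0.76).

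Of 820 values of 205 single genes 1 changed sign, Nrp1 under upper-quartile scaling (0.07 to -0.0012), and 172 moved beyond the read-counting interval. Other scalings shifted a gene by at most 0.0743 on the log2 scale.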

Other observations

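The tests of Esr1 against other cell types and fusion transcripts, of lymphocyte genes against purity, and of NK and B cell genes against chance sampling, were chosen after the result was seen, while the others were set out before the values they measure were looked at. Fkbp5, Tsc22d3, Klf9, Per2, Fbxo32 and Esr1 had by then been picked for their large ratios.

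Among the 10 most counted genes were several not described above. Lyz2, which encodes lysozyme, was 1.23-fold higher in the knockout library (1.21 to 1.25), Psap, the precursor of the saposins, 1.24-fold (1.21 to 1.26), the iron storage gene Fth1 1.29-fold (1.26 to 1.32) and Ctsb, cathepsin B, 1.21-fold (1.18 to 1.25). The translation factor gene Eef1a1 was 1.14-fold higher (1.11 to 1.17). Mitochondrial transcripts did not move together, with mt-Co1 1.22-fold higher (1.19 to 1.25) and mt-Cytb 1.39-fold lower (1.33 to 1.44).

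Glucocorticoid-responsive genes were higher in the knockout library. Fkbp5, Tsc22d3, Klf9, Per2 and Fbxo32, noticed among the largest differences, were 18.7-, 4.67-, 10.5-, 6.08- and 8.25-fold higher, and the lowest of their 5 lower bounds was 3.41-fold. Since these genes were picked for their large ratios, the bounds cannot decide on chance sampling of few amplified fragments. Of 16 further measured glucocorticoid-responsive genes, 13 were higher, 5 of them at least 2-fold, and their median of 0.88 lay at percentile 100, which is consistent with a general rise of such genes; Sgk1 was 1.8-fold (1.67 to 1.93), Per1 1.93-fold (1.67 to 2.24) and Slc10a6 42.2-fold (from 4.22) higher, and Cebpd, Bcl6 and Dusp10 were not. Clock output genes, which a different clock phase would have raised, lay at percentile 64.2 with 4 higher and 3 lower, and at 57.7 with the GC and length trend removed, but the 5 with at least 1000 counts lay at 97.6; genes of the opposite phase, which such a shift would lower, were higher in 4 of 5 cases (percentile 97.4), which goes against it, and with lists this small it stays open. Deletion of Nrp2, tamoxifen, the daily injections and the state of the animals are confounded here, so which of them the hypothesis of a glucocorticoid response belongs to stays open.

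Esr1 had 721 reads in the control library and 26006 in the knockout library. Chance sampling is argued against by a lower bound of 21.5-fold, though Esr1 was picked for its large ratio and the bound makes no allowance for that. Adipocytes, fibroblasts, endothelial cells, epithelial cells and keratinocytes as its source are argued against by their markers, in a comparison chosen after the result was seen. Esr1 gained 378 CPM, 4.15 times the largest gain among these markers, Scd1 at 91.0 CPM. Whether a shift among CD11b+ cell types raised Esr1 was not tested. The bead selection for CD11b is meant to remove other cells, yet T and B cell genes were read in both libraries and adipocyte genes were higher. Inducible recombinases are fused to part of an oestrogen receptor, and reads of a fusion transcript carried alike by both pools would not give a log2 ratio of 5.15. A fusion transcript present mainly in the knockout pool cannot be told apart from induction of Esr1 itself, because the 26006 reads are summed over the gene and no exon-level values were used; the labels give both pools the same genotype, so unequal carriage of the transgene would go against them, and a response to tamoxifen is a candidate explanation, untested.

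T, NK and B cell genes were lower in the knockout library. A higher purity of that pool would lower the genes of every other cell type. The epithelial, fibroblast, endothelial, keratinocyte and muscle medians (-0.87, -0.80, -1.01, -1.0 and -1.08) were in that direction. With members at their bounds they were -0.75 for epithelial, -0.69 for endothelial and -0.54 for muscle genes. The keratinocyte and muscle lists did not stand apart from matched random lists (percentiles 9.81 and 10.1), nor did the endothelial list at its bounds (2.74). The epithelial and fibroblast lists did, so a higher purity may account for part. The adipocyte list went the other way, at percentile 100, which a higher purity alone would not give. It was known to be higher when this test was chosen, so the test could not have come out otherwise. Its summed reads, 14695 and 31337, were 2.09-fold higher. Of the control reads Scd1 and Pnpla2 held 4715 and 5109, while Adipoq, Plin1 and Retn had 0 in that library. The sum is therefore not a measure of adipocytes alone. Chance sampling of few fragments is argued against for the summed T and B cell genes, whose ratios have upper bounds of 0.404 and 0.436. The summed NK genes were 1.55-fold lower with a bound of 0.714, which excludes 1 but misses the limit set for the T cell sum. Without Ccl5, the one member that another list holds, the NK sum was 2.90-fold lower with a bound of 0.413. That version met the limit but was chosen after the result was seen. Fewer lymphocytes in the tumours of the test group, or fewer carried along by the beads, may each account for the lower lymphocyte genes and stay open. Of the T, NK and B cell lists 2, 1 and 1 members are on another list.

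The interferon-inducible Gbp2b, looked at after Ifi202b, was 5.2-fold lower (3.61 to 7.61). Ddx3y, Uty, Eif2s3y and Kdm5d, all Y-linked, had at most 55 reads in either library, under the floor, while Xist was at 249 and 353 CPM. Pgr and Greb1, which oestrogen receptor signalling induces in other tissues, had 0 reads in both libraries.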
